A study of Mus musculus with 3 samples.

How the data were processed

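PATZ1, a zinc-finger transcription factor, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 10T1/2 cells, a mouse mesenchymal line that can turn into adipocytes, at day 0 and day 5 of differentiation. The labels give 1 PATZ1 library per day and 1 input library of sonicated chromatin that was not immunoprecipitated. Per the labels' protocols, chromatin was sheared by sonication, both days used an antibody against PATZ1 from Santa Cruz, and libraries were read single-end on an Illumina sequencer. The submitters' processing notes name Bowtie2 and HOMER, and the builds mm9, mm10 and GRCm38, without their roles. The peak caller and its settings are not given in the sources used here. The layout of the lists is the one MACS writes. The lists differ in extension length and in their weakest p, and whether the study's own results rest on the day 5 list as deposited is not given in the sources used here.

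The authors deposited a list of peaks and a list of summits for each day, so peaks were called per library and not on pooled samples. The score of each peak, as the authors deposited it, is 10 times its −log10 p, rounded down, in all but 1 day 0 peak. The fold of each peak is the authors' deposited ratio of piled-up reads to the local background at the summit, with 1 added to both, which lowers it most where the background is small, as at day 5. The −log10 p and −log10 q of each peak are the authors' deposited values, and the summit lists repeat the −log10 p. These values were used to describe, rank and filter peaks within a list, and are not read as a change between days. Coordinates are mm9: of 20 chromosomes compared with the known lengths of the builds, 9 have a peak past the end in mm10 and 0 past the end in mm9. The gene table at hand is of GRCm38, and coordinates were not converted between builds. Classes of genomic position, genes with a promoter peak, the gene lists chosen beforehand and sequence words at summits were therefore not analysed here.

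The number of reads piled up at each summit and the background it was compared with were solved from the deposited fold and −log10 p, as (pile-up + 1) / (background + 1) and a Poisson tail. A whole number of reads met both values within a relative difference of 0.0001 for all but 1 of the 315100 day 0 peaks and for all of the 852421 day 5 peaks. Tested on simulated data, 99.97% of 20000 day 0-like and 99.99% of 20000 day 5-like peaks gave back their pile-up. The lowest background divided by the narrowest peak width, taken as the length to which reads were extended, gives the depth over the caller's genome. It was 8.55 reads per kb at day 0 (extension 228 bp) and 8.07 reads per kb at day 5 (extension 56 bp). The background steps by 0.906 reads per control read at day 0 and 0.855 at day 5, which gives 9.44 control reads per kb in each list, so control libraries of the same size entered both. The total number of reads per library is not given in the sources used here.

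Overlap was counted as at least 1 bp shared with a peak of the other day on chromosomes 1 to 19, X and Y. It was compared with 100 placements of the other list at random between the first and last peak of each chromosome. Assembly gaps were not left out of that span, which can lower the random level. Counts of overlapping peaks equalled those of bedtools 2.31.1, with a difference of 0. Shares have 95% Wilson intervals, which treat peaks as independent and cover counting error only. To see what chance alone gives with a common control, pairs of libraries without enrichment were simulated in 10 runs of 20 Mb each, at the depths and extension lengths above, with p limits of 0.1 for day 0 and 0.05 for day 5, read off the weakest peaks of each list. The genome of these simulations is even, without differences in copies or mappability. In 2 further runs at each of 7 levels, the control alone was scaled from 0.25 to 3 times. With 1 library per day there is no replicate check of any difference between days, no test was made between them and no p-value is given.

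The peak counts, the overlap and their alternatives were chosen before the data were examined. These were stricter limits on −log10 q, equal numbers of peaks, the 20000 strongest peaks, distinct or merged intervals, reciprocal overlap of 50%, summits within 100 bp and chromosomes 1 to 19 alone. A q of at most 0.05, a p of at most 0.05, a limit of 5 on −log10 p, and windows moved by 10000 and 20000 bp from the summit were added after seeing the data. The rule for named genes, set beforehand, took the 10 genes with the highest −log10 p of each day and the 10 of each day alone. Without genes it was carried over to peaks: the 10 with the highest −log10 p in each list on the chromosomes used for overlap, and the 10 highest with no overlapping peak of the other day. Other regions in the text were chosen after their values were seen. Columns not used number 0. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.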

Results

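PATZ1 occupancy was surveyed at day 0, in undifferentiated 10T1/2 cells, and at day 5 of differentiation. The study asks where in the genome PATZ1 binds on each of these days. The deposited lists hold 315100 peaks at day 0 and 852421 peaks at day 5, from 1 library per day. Depth was close in both libraries, at 8.55 reads per kb at day 0 and 8.07 reads per kb at day 5, a ratio of 0.944. At this depth, and with extensions of 228 bp at day 0 and 56 bp at day 5, the median summit rested on 7 and 3 reads. Positions are in mm9, and the genes at them are not analysed here.

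At day 0, a set of broad, tall peaks stood out from a much larger number of weak ones. The strongest lay on chromosome 13 from 63801535 to 63802964, where 219 reads piled up over a background of 3.27, an authors' fold of 51.6. Another on chromosome 13, from 21418079 to 21419648, held 245 reads with a fold of 33.5, and one on chromosome 6, from 35272988 to 35273866, held 181 reads with a fold of 48.9. A peak on chromosome 16 from 14884773 to 14885586 held 164 reads with a fold of 40.2. The 10 day 0 peaks with the highest −log10 p had folds from 10.5 to 51.6 and pile-ups from 113 to 245 reads.

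The other 6 of these 10 lay on chromosomes 3, 5, 6 and 15. Chromosome 15 carried 3 of them: 52759810 to 52760587 with 150 reads, 102023002 to 102024331 with 166 reads, and 81702008 to 81702828 with 219 reads over a background of 19.9. The peak on chromosome 5 from 23224656 to 23225467 held 122 reads, that on chromosome 6 from 29276254 to 29277827 held 113 reads, and that on chromosome 3 from 103397308 to 103398636 held 138 reads. These peaks were 778 to 1574 bp wide, against a median of 277 bp for the day 0 list.

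Of the day 0 peaks, 6570 had a q of at most 0.05, 814 a −log10 q of at least 5, 372 of at least 10 and 144 of at least 20. The 814 peaks with −log10 q of at least 5 had a median width of 642 bp, a median pile-up of 34 reads and a median fold of 4.97. They lay on all 20 chromosomes with day 0 peaks, with 103 on chromosome 15, 71 on chromosome 11, 66 on chromosome 4, 57 on chromosome 3 and 13 each on chromosomes 18 and X. The 1-Mb window with the most, chromosome 15 from 102000001 to 103000000, held 11 of them. Windows on chromosome 15 from 78000001 and on chromosome 4 from 140000001 held 8 each, and those on chromosome 15 from 85000001 and 98000001 and on chromosome 5 from 137000001 held 7 each. Of 794 pairs of neighbouring strong peaks on a chromosome, 73 lay within 50 kb of each other. At the other end of the list, 275811 peaks had a −log10 q below 0.5, with a median pile-up of 7 reads over a background of 2.71.

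**Figure D1:**
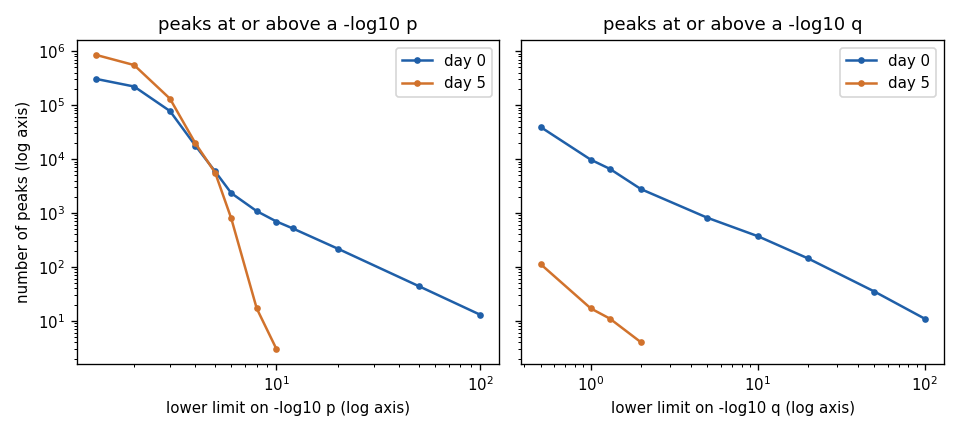
Number of peaks (log axis) at or above a limit on −log10 p (left) or −log10 q (right; both limits on log axes) in the day 0 list and the day 5 list, 1 library each. The day 5 list is longer at low limits and ends by a −log10 p of 11.5, while 218 day 0 peaks reach 20 or more.

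At day 5, the list held more peaks than at day 0, but at its extension of 56 bp almost none of them had a low q. Its highest −log10 p was 11.5, its highest fold 6.47, and 11 of the 852421 peaks had a q of at most 0.05, 4 a −log10 q of at least 2 and 0 of at least 5. Day 5 peaks were 56 to 518 bp wide, with a median of 59 bp, and 84.6% of them had a −log10 q of 0. The top day 5 peak, on chromosome 2 from 98507385 to 98507442, held 106 reads over a background of 50.4. It belongs to a group of 9 day 5 peaks between 98502405 and 98507442 whose backgrounds ranged from 33.3 to 75.2 reads and whose folds ranged from 1.34 to 2.08. The day 0 list holds 2 peaks in this stretch. The day 0 peak that overlaps the day 5 peak starting at 98506735 held 275 reads at a fold of 1.12.

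Among the other day 5 peaks with the highest −log10 p, the one on chromosome X from 166444970 to 166445026 held 15 reads over a background of 1.71. It lay 1305 bp before the last peak end of either list on that chromosome. Peaks on chromosome 19 from 61261234 to 61261337 and on chromosome 1 from 58670814 to 58670871 held 11 and 14 reads. A peak on chromosome 17 from 36368227 to 36368282 held 48 reads over a background of 18.0. Peaks on chromosome 1 from 88688450 to 88688601, on chromosome 12 from 92363277 to 92363366, on chromosome 13 from 28282480 to 28282615 and on chromosome 10 from 14792913 to 14792986 held 8 reads each. Of the day 5 peaks with no overlapping day 0 peak, those on chromosome 4 from 3016900 to 3016962, on chromosome 6 from 71189606 to 71189703 and on chromosome 17 from 60611382 to 60611478 completed the 10 with the highest −log10 p. The chromosome 4 peak lay over a background of 16.2 reads, near a day 0 summit at 3017930 with 103 reads.

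The order of the days depended on the limit. Without one, the day 5 list was 2.71 times as long as the day 0 list. At a −log10 p of at least 5, day 0 had 5880 peaks and day 5 had 5592, and at 6 they had 2333 and 791. Simulated libraries with no enrichment gave 121.1 peaks per Mb with day 0 settings and 332.1 with day 5 settings, beside 119.3 and 322.7 per Mb in the lists. The simulated peaks lay on lower backgrounds than the listed ones, so this is a match in number only. At a −log10 p of at least 6, the simulated libraries gave 0.0175 peaks per Mb with day 0 settings against 0.883 listed, and 0.292 with day 5 settings against 0.299 listed. At a limit of 4 the day 5 list exceeded the simulated libraries, with 7.39 against 4.998 per Mb, and at 5 it lay below them, with 2.12 against 2.56. The lists differed in extension length and in their weakest −log10 p, 1.005 at day 0 and 1.303 at day 5, so their lengths do not measure the number of bound sites. A shorter extension also piles up fewer reads at a site, so one limit on −log10 p or q is not equally strict in both lists.

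The comparison of both days showed that the strongest day 0 regions were not strong at day 5. Of the 10 highest day 0 peaks, 7 overlapped a day 5 peak, against a mean of 3.72 and up to 7 in 100 random placements, and the day 5 pile-up there was 2 to 7 reads. On chromosome 13, the 245 reads of the day 0 peak at 21418079 scale to 56.8 at the day 5 extension length and depth, and the day 5 pile-up was at most 7. For the peak at 63801535 the 219 reads scale to 50.8, and the day 5 pile-up was at most 4. No day 5 peak was listed at the chromosome 6 peak starting at 35272988, nor at the chromosome 15 peaks starting at 102023002 and 81702008. Day 0 peaks without a listed day 5 peak also included those on chromosome 2 from 26428298 to 26429268 with 94 reads, on chromosome 3 from 103613181 to 103613704 with 132 reads, on chromosome 4 from 15921498 to 15922181 with 89 reads and on chromosome 12 from 3806183 to 3806987 with 115 reads. The remaining 3 of the 10 highest such peaks were on chromosome 15, starting at 85430560, 102087413 and 78675067.

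Over the 144 day 0 peaks with −log10 q of at least 20, 67 (46.5%, 95% Wilson interval 38.6 to 54.7) overlapped a day 5 peak and 77 did not, against a mean of 28.7% (21.5 to 38.9) in random placements. At −log10 q of at least 10 the share was 41.7% against 26.0% at random, and at 5 it was 35.7% against 24.2%. The median day 0 pile-up at these sites was 63.5 reads, and scaled to the day 5 extension length and depth it was 14.7. Where a day 5 peak was listed, its median pile-up was 4 reads and the highest was 10. The scaled value was reached at 0 of the 144 sites, and 50% of it at 4 sites (2.78%, 1.09 to 6.92). Among the 814 peaks with −log10 q of at least 5, 14 reached the scaled value and 177 (21.7%, 19.05 to 24.7) reached 50% of it, with a day 5 peak listed at 291. The median scaled value of the 814 was 7.88 reads, and the median peak of the whole day 5 list held 3. A weak day 5 peak can therefore reach 50% of the scaled value where the day 0 pile-up was low. Sites with no listed day 5 peak have an unknown pile-up and count as not reaching either value. With 1 library per day, this difference has no replicate check.

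**Figure D2:**
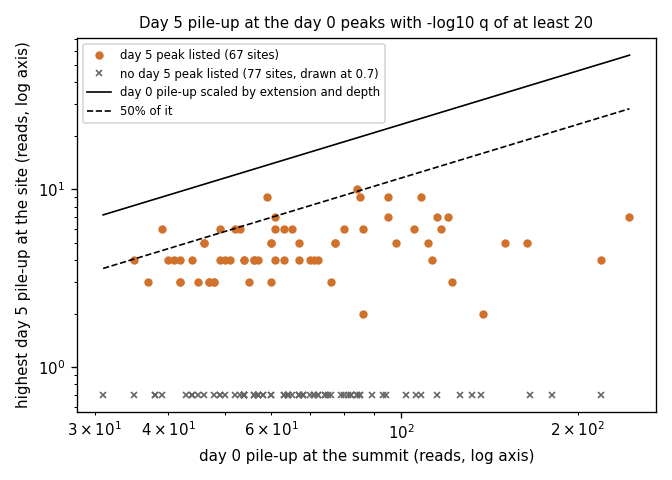
Highest day 5 pile-up (reads, log axis) against day 0 pile-up (reads, log axis) at the 144 day 0 peaks with −log10 q of at least 20; crosses mark the 77 sites with no day 5 peak listed, the solid line the day 0 pile-up scaled by extension length and depth, and the dashed line 50% of it. All points for listed day 5 peaks lie below the solid line, and 4 reach the dashed line. The pile-up at the crosses is not known.

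Over the whole lists, 22.1% of day 0 peaks (69575 of 315100, 95% Wilson interval 21.9 to 22.2) overlapped a day 5 peak, against a mean of 12.7% (12.6 to 12.9) in 100 random placements, a ratio of 1.73. Conversely, 8.84% of day 5 peaks (8.78 to 8.90) overlapped a day 0 peak, against 4.92%, a ratio of 1.80. Both lists were called against a control of the same size, and a common control by itself makes lists coincide. Simulated libraries with no enrichment gave a ratio of 1.31 ± 0.0554 (SD over 10 runs) with a common control and 1.03 ± 0.0861 with separate controls, so part of the excess may come from the shared control. Strong day 0 peaks were wider, and both their share of overlap and its random level were higher than over the whole list. The share of day 0 summits with a day 5 summit within 150 bp showed no steady rise with day 0 strength. Day 5 summits lay within 150 bp of 16.5% of day 0 summits with −log10 q below 0.5 (16.3 to 16.6), of 19.3% of those with a q of at most 0.05 and a −log10 q below 5 (18.3 to 20.4), of 15.2% of those with −log10 q from 5 to 10 (12.1 to 18.8) and of 22.2% of those of at least 20 (16.2 to 29.7). Windows moved by 10000 or 20000 bp held a day 5 summit in 10.95%, 11.5%, 11.3% and 11.98% of cases.

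**Figure D3:**
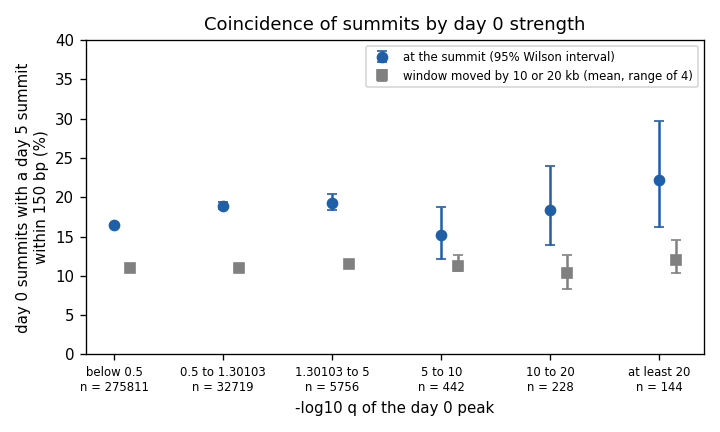
Percent of day 0 summits with a day 5 summit within 150 bp, by −log10 q of the day 0 peak (circles, 95% Wilson intervals), and the same for windows moved by 10 or 20 kb (squares, mean and range of 4). The share at the summit stays between 15.2% and 22.2%, above the mean of the moved windows in every class. At −log10 q from 5 to 10 its interval (12.1 to 18.8) overlaps the range of the moved windows (up to 12.7%).

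Densities were taken over the 20 chromosomes with day 0 peaks, which leaves out chromosomes Y and M. Day 0 peaks were spread unevenly over them, from 17.0 per Mb on chromosome X to 258.3 on chromosome 15. That is a range of 15.2 times. Chromosomes 13, 3 and 4 followed chromosome 15 with 238.8, 227.1 and 195.6 per Mb, and chromosomes 10 and 12 were low with 49.3 and 55.8. Over the same chromosomes, day 5 peaks ranged over 2.80 times, from 152.3 per Mb on chromosome 7 to 425.8 on chromosome 15, and chromosome 10 was second with 417.5. Across the 20 chromosomes, which are not independent replicates, the densities of both lists had a Spearman rho of 0.4496 and a Pearson r of 0.422, or an r of 0.256 without chromosomes 13 and 15. On chromosome X, day 0 had 7.86 peaks per Mb before 130 Mb and 50.5 after it, a step of 6.42 times at a place chosen after seeing the density. The day 0 peaks per 5-Mb window ranged from 0 to 71 in the 26 windows before it and from 151 to 343 in the 7 after it. The day 5 step at the same place was 1.26 times.

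**Figure D4:**
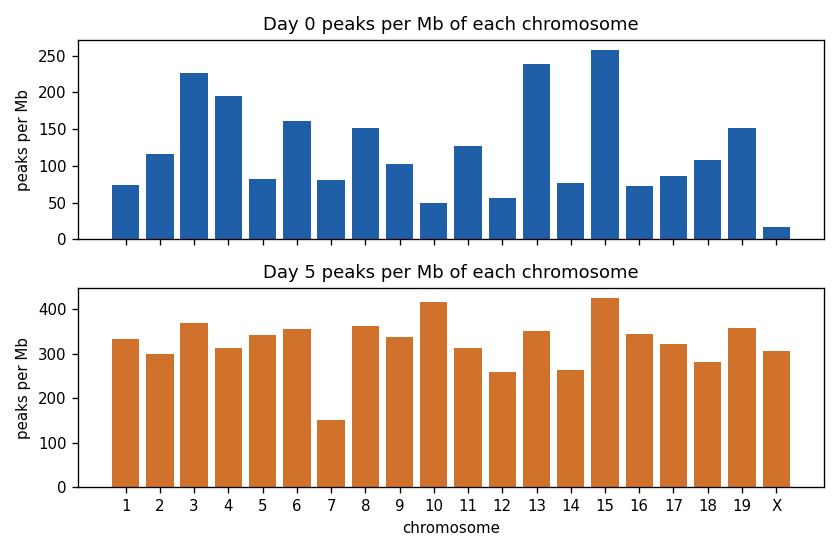
Peaks per Mb of the 20 chromosomes with day 0 peaks, in the day 0 list (top) and the day 5 list (bottom). Each list is from 1 library, and the axes start at 0. Chromosomes Y and M, with 0 day 0 peaks, are left out of the ranges. Day 0 ranges from 17.0 on chromosome X to 258.3 on chromosome 15, and day 5 from 152.3 on chromosome 7 to 425.8 on chromosome 15.

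**Figure D5:**
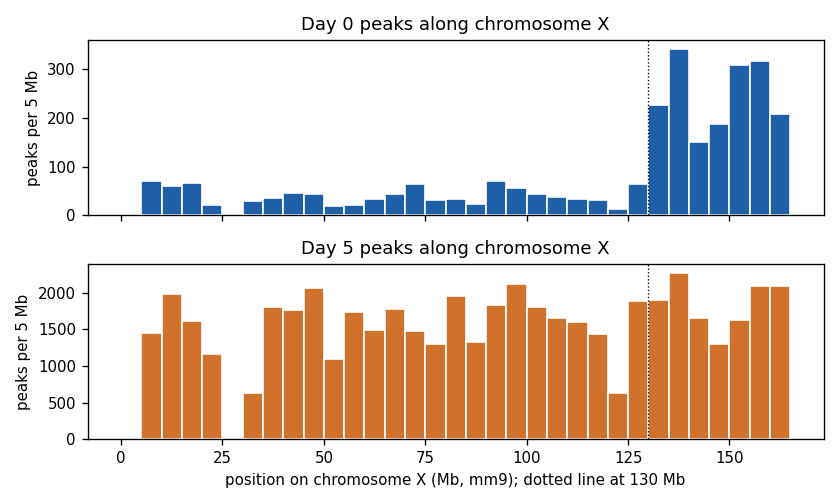
Number of peaks in 5-Mb windows along chromosome X (position in Mb, mm9) at day 0 (top) and day 5 (bottom), with a dotted line at 130 Mb. Day 0 rises from 7.86 to 50.5 peaks per Mb at the line, and day 5 from 296.8 to 372.6.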

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

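The chromosome M and Y values and the tests weighed here were chosen after the results were seen, except the simulated libraries without enrichment, whose tests were set before their outcome. The day 5 list holds 4 peaks on chromosome M, which the comparisons do not use, and the day 0 list holds 0. Their pile-ups of 103 to 110 reads stood 1.25 to 1.36 fold over the control background, and their highest −log10 q was 0.0147. Chromosome Y, which the overlap does use, has 46 day 5 peaks and 0 day 0 peaks.

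The day 5 list is longer than the day 0 list and yet nearly lacks peaks with a low q. The depth of the libraries argues against lower sequencing at day 5, which has 0.944 of the reads per bp of day 0. The shorter extension was weighed by taking pile-ups to fall in proportion to it. Of the 144 strongest day 0 sites, 67 had a listed day 5 peak and 4 (2.78% of the 144) reached 50% of the scaled pile-up. That argues against the extension alone at the 67 sites. With −log10 q of at least 10, 57 of the 155 listed sites reached it (15.3% of 372). With at least 5, 177 of the 291 listed sites did (21.7% of 814). In these wider sets 50% of the scaled pile-up is often only a few reads, which a weak day 5 peak also holds, so they do not decide. At sites with no listed day 5 peak the pile-up is not known, and they count as not reaching it. Chance pile-ups past a loose p may account for the lengths of the lists: simulated libraries with no enrichment gave 2.74 times as many day 5 as day 0 peaks, beside 2.71 times in the lists. That match is of genome averages on an even genome. The listed day 0 density runs from 17.0 to 258.3 per Mb over the 20 chromosomes with day 0 peaks. Why strong day 0 sites are weak at day 5 stays open: less PATZ1 on chromatin at day 5, a weak immunoprecipitation and a wrong label cannot be told apart with 1 library per day, and whether the study's own results rest on this day 5 list, with its 56 bp extension, is not known here.

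Day 0 and day 5 peaks coincide more often than random placement gives, by a ratio of 1.73. For summits, 16.8% at day 0 had a day 5 summit within 150 bp, against 10.97% in moved windows, a ratio of 1.53. Both the measure and the comparison differ there from those behind 1.73. With summits within 100 bp against random placement the ratio was 1.76. Occupancy kept at the day 0 sites stays open: 22.2% of the strongest summits have a day 5 summit within 150 bp, 1.86 times the level of moved windows (11.98%), and a weak day 5 immunoprecipitation could hold the share down. A common control library is a candidate explanation for part of the excess. At day 0 peaks whose background was 3 control reads, the share with a day 5 summit differed by -2.63 percentage points at the site from 300 bp away, while at peaks with the lowest background it was higher at the site (15.7%) than 300 bp away (12.6%). Whether the control gives the whole excess stays open, since simulated libraries on an even genome reached a ratio of 1.31, and uneven read coverage of the real genome was not simulated.

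Day 0 peak density differs between chromosomes and steps up on chromosome X. A change in the control alone would need less control coverage after 130 Mb, and the share of day 5 peaks at the lowest background argues against that, with 26.9% before it and 11.8% after it (-15.1 percentage points). In simulated libraries, the scaling of the control chosen for the day 0 step nearest the observed 6.42 gave 6.78 at day 0 and 1.66 at day 5. The day 5 value is past the limit set beforehand, the upper bound of 1.28 of the observed day 5 step. With 7 control levels on an even genome, this simulated step alone excludes nothing. More day 0 reads on some chromosomes, as from extra copies in the day 0 cells, could contribute: the ratio of peaks with 8 piled reads to peaks with 7 at the lowest background rose with day 0 density across the 20 chromosomes (Spearman rho 0.871, Pearson r 0.873, r 0.824 without chromosomes 13 and 15), but the like ratio of 4 to 3 reads rose with day 5 density too (rho 0.814, r 0.861). Both days used the same line, and copies common to both days would act on both lists, whose densities had a rho of 0.4496. Day 0 peaks with −log10 q of at least 5 were also denser where all day 0 peaks were (rho 0.731, r 0.694, r 0.562 without chromosomes 13 and 15), and extra copies and a difference in PATZ1 binding between chromosomes cannot be told apart.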

How the results depend on the processing

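A q of at most 0.05, a p of at most 0.05 and a −log10 p of at least 5 were chosen after seeing the data, as were the moved windows. Distinct intervals and merged regions gave the same numbers of peaks as the lists, and chromosomes 1 to 19 alone left the day 0 share and its ratio within their intervals. The surplus of 537321 day 5 peaks turned into a surplus at day 0 under stricter limits. With −log10 q of at least 5 there were 814 day 0 and 0 day 5 peaks (difference -814), at 10 there were 372 and 0 (-372), both past the highest day 5 value of 3.06, at a q of at most 0.05 there were 6570 and 11 (-6559), and with −log10 p of at least 5 there were 5880 and 5592 (-288). One limit is not equally strict at the extension lengths of both lists, and the cause of the last 2 was not tested. Equal numbers (315100 each) and the 20000 strongest of each list make the difference 0. The share of day 0 peaks overlapping day 5, 22.1%, became 0% at −log10 q of at least 5 and of 10, 8.75% with equal numbers, 1.02% with 20000 peaks, 0.752% with reciprocal overlap, 11.7% with summits within 100 bp, 0.0152% at a q of at most 0.05, 22.2% at a p of at most 0.05 and 0.289% at −log10 p of at least 5. The share of day 5 peaks overlapping day 0, 8.84%, became 9.07% with equal numbers, 1.03% with 20000 peaks, 0.278% with reciprocal overlap, 4.38% with summits within 100 bp, 9.30% on chromosomes 1 to 19, 9.09% (1 of 11 peaks) at a q of at most 0.05, 8.64% at a p of at most 0.05 and 0.304% at −log10 p of at least 5. The ratio of the day 0 overlap to its random level, 1.73, stayed above 1 in each setting that gave one: 1.78 with equal numbers, 2.04 with 20000 peaks, 2.27 with reciprocal overlap, 1.76 with summits within 100 bp and 2.00 at −log10 p of at least 5. That last ratio rests on 17 peaks: random placements reached the observed day 0 share (0.289%) and passed the day 5 share (0.304%, against up to 0.322%). Shares fall with fewer peaks or a narrower match by construction, and the cause of the changes in the ratio was not tested. At −log10 q of at least 5 and 10 the day 5 share and the ratio have no value, and at a q of at most 0.05 the ratio has none because the random level is under 1 peak. The alternatives for genomic classes, promoter peaks, gene lists and sequence words were not run. No paired analysis was possible because each day has 1 library. Depth and extension length limit the weak peaks, whose median rests on 7 reads at day 0 and 3 at day 5.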

Other observations

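All tests in this part, the counts of simulated peaks by −log10 p included, were chosen after results were seen. The day 0 list moves away from simulated libraries without enrichment step by step. At a −log10 p of at least 2 it holds 83.7 peaks per Mb and they hold 86.7, at 4 the values were 6.70 and 2.63, at 5 they were 2.23 and 0.45, and at 6 they were 0.883 and 0.0175. The day 5 list lies nearer to its simulated libraries but not on them, with 49.8 against 43.3 per Mb at 3, 7.39 against 4.998 at 4, 2.12 against 2.56 at 5 and 0.299 against 0.292 at 6. The highest −log10 p in 400 simulated Mb was 7.67 with day 0 settings and 7.66 with day 5 settings. At 8 or above the day 0 list holds 0.410 peaks per Mb (1082 in all) and the simulated libraries 0. The day 5 list holds 0.00644 per Mb (17 in all) there, too few for 400 simulated Mb to set them apart from chance.

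Along the genome, the day 0 list was more uneven than the day 5 list. Over 519 windows of 5 Mb, the coefficient of variation of the number of peaks was 65.7% at day 0 and 28.4% at day 5. Day 5 peak density went with the median background at the listed day 5 peaks of the chromosome (Spearman rho 0.913, Pearson r 0.897), and day 0 density with that at the listed day 0 peaks less closely (rho 0.491, r 0.548, or r 0.283 without chromosomes 13 and 15). The median backgrounds of both lists ordered the chromosomes nearly alike (rho 0.980). These are 8 relations across 20 chromosomes, and no p was computed for them.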
